A study of Mus musculus with 6 samples.

How the data were processed

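The data were signals from Affymetrix MOE430 2.0 mouse arrays, which read each transcript with sets of short oligonucleotide probes. Per the labels' protocols, total RNA was extracted from whole colon with Trizol, biotinylated cRNA was made from it, and each sample was hybridised to its own array with a single label. There were 6 arrays: 3 from wild-type mice (NHE3+/+) and 3 from NHE3-deficient littermates (NHE3-/-), all 6 to 8 weeks old. How many animals contributed to an array and their sex were not given in the sources used here.

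The deposited values are intensity values on a linear scale, 1 signal per probe set and array. The submitters' processing notes name GCOS, the Affymetrix operating software, without a version. Algorithm settings and detection calls were not given in the sources used here. The values show a global scaling by the authors: the mean left after trimming 2% from each end was 500 on each array. Values ran from 0.1 to 68917. The median signal was 99.7, 121.4 and 106.9 on wild-type arrays 1, 2 and 3, and 97.8, 99 and 103.9 on NHE3-deficient arrays 1, 2 and 3. The scale is linear, the arrays are not centred, and a direction of ratios does not apply to single-label arrays. The scaling settings of the software stay unknown. No read depth applies to arrays, and the number of arrays limits the precision.

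From these intensity values, log2(signal + 31.4) was computed, the pseudocount being the 25th percentile of all deposited values. Fold changes are on this scale, which understates the change of dim transcripts. Of 45101 probe sets, the 64 array controls and those with a mean log2 value under the 40th percentile were left out, and 27024 were tested. No further normalization was applied. The comparison of NHE3-deficient with wild-type colon used limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend, genotype as the only term, two-sided). P-values were adjusted by the Benjamini-Hochberg method over the probe sets tested, with a threshold of 0.05. Errors of log2 fold changes are limma's standard errors (SE). On simulated data of 27024 probe sets with 200 changed, this fit recovered 35% of those changed by a log2 size of 1 and 85% of those changed by a log2 size of 2. In that simulation 9 of 129 calls were false and none had the wrong sign. It changed far fewer probe sets than were called here and used independent noise, so these rates may not hold for the real comparison.

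Gene names came from the platform annotation, in which 34958 probe sets name 1 gene, 932 several and 9211 none. Gene IDs of 34754 of these 34958 probe sets matched a RefSeq table of assembly GRCm38.p6, used only for current symbols and for which genes lie near each other. No gene was named from a probe set with several. Within the gene lists, a gene was represented by its probe set of highest mean log2 signal among those naming that gene alone, chosen over all 6 arrays and kept where arrays were left out.

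The 30 gene lists, the tests, the thresholds, most alternative settings and the rule for naming genes were fixed before the data were examined. The lists hold 562 genes. They cover sodium and potassium channels and the aldosterone response, ion exchangers and epithelial transporters, the interferon response, antigen processing and presentation, antimicrobial and epithelial defence, and inflammatory cytokines, chemokines and adhesion. Further lists cover tight junctions and epithelial adhesion, detoxification and nuclear receptor targets, fatty acid oxidation and ketogenesis, cholesterol synthesis, endoplasmic reticulum stress, the circadian clock, and X-inactivation and the Y chromosome. The remaining lists hold markers of proliferation, stem and crypt base cells, absorptive colonocytes, goblet cells and mucus, and enteroendocrine cells. They also hold markers of T cells and cytotoxic lymphocytes, B cells and plasma cells, macrophages and dendritic cells, neutrophils and mast cells, smooth muscle, enteric neurons and glia, and fibroblasts and matrix. The last lists hold markers of endothelium, adipose tissue, pancreas, small intestine and red blood cells. List genes without a probe set of their own past the filter were not analysed here.

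Lists were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. These p-values were adjusted by the Benjamini-Hochberg method over the 30 lists. Where a range of adjusted p over the alternatives is given for a list, it is that of camera at the preset correlation. Camera compares a list with the other genes, while fry tests whether its genes move, on balance, 1 way and makes no such comparison. For 4 further lists of the closing section, drawn up later (posterior Hox, anterior Hox, iron shortage, and amino acid and peptide absorption), fry p-values were adjusted over these 4. Members were also counted with p-values adjusted over the list alone. The rule for names took Slc9a3, the 15 largest changes in each direction among called probe sets that name 1 gene and whose groups do not overlap, up to 6 members of smallest p in each list, any member as an example of a count, and the 3'/5' controls of RNA quality. Called probe sets near Slc9a3 were compared with all others by Fisher's exact test within 20 Mb.

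Alternatives were other pseudocounts, other filters, quantile normalization, medians set equal on all arrays, no mean-variance trend, array weights, a plain equal-variance test, the replicate number as a block, each array left out, other thresholds, other windows and the mean over all probe sets of a gene. A fit with only the NHE3-deficient array without Xist signal and a fit with the log2 Xist signal as a covariate were added after the data had been seen, as were repeats of 2 closing lists without some of their members.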

Results

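Gene expression was measured in whole colon of mice lacking NHE3, the sodium-hydrogen exchanger encoded by Slc9a3, which takes up sodium across the luminal membrane of the intestinal epithelium. The question was which colonic transcripts differ between these mice and their wild-type littermates. There were 3 arrays per genotype, and the labels do not say that each came from a separate animal, so p-values measure the spread between these samples, which may be technical. Correlations of log2 signals across probe sets were 0.969 to 0.970 within the wild-type group, 0.965 to 0.973 within the NHE3-deficient group and 0.932 to 0.959 for the 9 pairs between groups. The first principal component held 46.4% of the variance and separated the genotypes. Its scores were negative for the wild-type arrays and positive for the NHE3-deficient arrays. On the second (15.9%), NHE3-deficient array 3 scored -37.7, against 24.6 and 24.9 for arrays 1 and 2 of its group. Wild-type arrays lay between -17.1 and 18.4 there. The 3'/5' signal ratio of the Gapdh control, a measure of RNA integrity, was 0.812 ± 0.0779 (SD, n = 3) in wild type and 0.755 ± 0.0220 (SD, n = 3) in NHE3-deficient colon (exact permutation test, two-sided p = 0.4). The Actb ratio was 1.38 ± 0.141 and 1.22 ± 0.0428 (SD, n = 3 each; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays allow).

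Slc9a3 itself was read by 2 probe sets. The brighter had a signal of 6075 ± 531 (SD, n = 3) in wild type and 4634 ± 1196 (SD, n = 3) in NHE3-deficient colon, a log2 fold change of -0.42 (SE 0.16; adjusted p = 0.120). The dimmer had 266 ± 137 and 449 ± 173 (SD, n = 3 each), a log2 fold change of 0.76 (SE 0.39; adjusted p = 0.230). Neither passed the threshold. The labels do not say which part of the gene is disrupted, so a probe set outside that part checks nothing. For the brighter probe set the log2 fold change was -0.61 (adjusted p = 0.0199) without NHE3-deficient array 1, -0.72 (adjusted p = 0.0276) with NHE3-deficient array 3 alone and -0.76 (adjusted p = 0.0381) with the Xist signal as a covariate. Over all alternatives the adjusted p ran from 0.0199 to 0.360. Signals of the brighter probe set lay between 3665 and 5970 on the arrays labelled NHE3-deficient.

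The arrays differed in transcripts that mark sex. Xist, the RNA that coats the inactive X chromosome of female cells, had signals of 2639 and 1929 on NHE3-deficient arrays 1 and 2. It had 12.3 on NHE3-deficient array 3 and 4.3, 8 and 2 on the wild-type arrays. Eif2s3y, a Y-linked translation factor gene, was detected on every array, at 1434, 1457 and 1809 in wild type and at 932.6, 1088 and 1355 on NHE3-deficient arrays 1, 2 and 3. The signal of Kdm5d, a Y-linked histone demethylase gene, was 0.464, 0.552 and 0.997 times the wild-type mean on those 3 arrays. In the list of X-inactivation and Y chromosome genes, 0 of 4 measured members passed the limma threshold through their representative probe sets, and 2 were lower when adjusted over the list alone. The mean log2 fold change of that list was 0.18, its median -0.16, and camera gave a downward direction (adjusted p = 0.772). Without NHE3-deficient array 3, which had no Xist signal, 1 member was higher and 2 were lower and the mean was 0.34. It was 0.11 without NHE3-deficient array 1 and 0.079 without array 2 of that group.

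**Figure D1:**
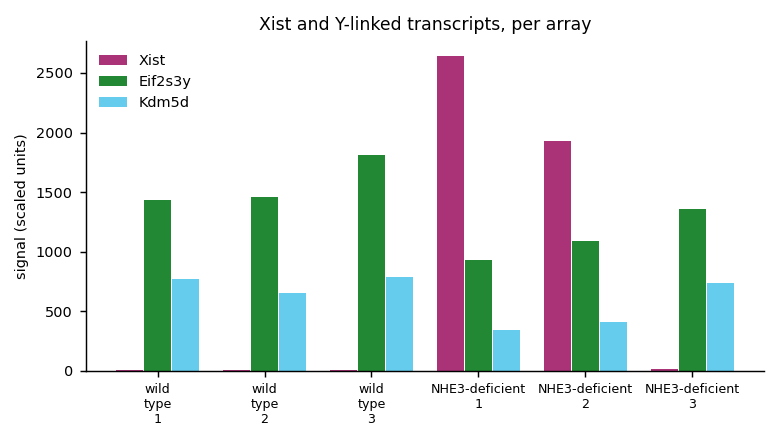
Signals (scaled units, linear axis) of Xist and of the Y-linked genes Eif2s3y and Kdm5d on each of the 6 arrays, 1 bar per gene and array. NHE3-deficient arrays 1 and 2 held Xist signals of 2639 and 1929 together with Y-linked signal, and the other 4 arrays held Xist signals of 12.3 or less.

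The largest increases in NHE3-deficient colon included genes of sodium and potassium transport. Scnn1g, the gamma subunit of the epithelial sodium channel, rose from a signal of 12.1 ± 5.91 to 2744 ± 761 (SD, n = 3 each), a log2 fold change of 5.97 (SE 0.23). Fxyd4, a regulator of the sodium pump, rose from 757 ± 353 to 27470 ± 8068 (log2 fold change 5.17, SE 0.27), and Atp12a, the colonic hydrogen-potassium pump, from 4203 ± 602 to 43968 ± 8337 (3.37, SE 0.15). The calcium-activated chloride channel regulator Clca4b rose by a log2 fold change of 5.01 (SE 0.32). Genes of defence and of the surface epithelium also rose: S100a8, a calprotectin subunit (4.20, SE 0.39), Defb1, a beta-defensin (4.05, SE 0.27), Casp14, a caspase of cornifying epithelium (4.22, SE 0.16), and Ubd, a ubiquitin-like modifier induced by cytokines (3.18, SE 0.31). Among transporters of amino acids, Slc7a9 rose by 3.91 (SE 0.22) and Slc6a19 by 3.25 (SE 0.19), and the brush border aminopeptidase Anpep rose by 3.08 (SE 0.29). Plat, tissue plasminogen activator (3.50, SE 0.20), Steap4, a metalloreductase (3.49, SE 0.46), and 2010106E10Rik (3.28, SE 0.29) complete the 15 largest increases together with the Xist probe set of larger change (4.08, SE 1.17, adjusted p = 0.0475). The Xist call was lost when any of wild-type arrays 1, 2 or 3 was left out (log2 fold changes 4.08, 4.15 and 4.03), with quantile normalization (4.07) or without a filter. Another Casp14 probe set had 1.47. The other Xist probe set had 1.63 and was not called. For the other 14 genes the adjusted p ranged up to 0.000951 for Steap4.

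The largest decrease was that of Ang4, an antimicrobial ribonuclease of secretory cells, which fell from 8690 ± 1914 to 332 ± 112 (SD, n = 3 each), a log2 fold change of -4.61 (SE 0.22). Mptx1, a mucosal pentraxin of the colon, fell from 20300 ± 3968 to 2071 ± 483 (-3.28, SE 0.17), and Itln1, a lectin that binds microbial sugars, had a log2 fold change of -2.77 (SE 0.34). The interferon-inducible Ifi27l2a had -3.73 (SE 0.33), Ccn3, a secreted matricellular protein, -3.47 (SE 0.21), Tppp3 -2.21 (SE 0.23), Bex1 -2.01 (SE 0.20), Pla2g4c, a cytosolic phospholipase, -2.57 (SE 0.42) and H60c, a ligand of the receptor NKG2D, -2.10 (SE 0.35). The list also holds the pancreatic lipase cofactor Clps (-2.77, SE 0.24), the lipase-related Pnliprp2 (-2.21, SE 0.46), the adipocyte genes Fabp4 (-2.60, SE 0.31) and Car3 (-2.42, SE 0.52), Serpina1b (-2.03, SE 0.50) and the IgE receptor gene Fcer2a of B cells, which fell from 350 ± 211 to 56.7 ± 28.4 (SD, n = 3 each). Other probe sets of Pla2g4c and Car3 had smaller falls, of -0.62 and -1.02. Car3 was no longer called without wild-type array 2 (-1.85), where its signal was 3308 against 1134 and 896.5 on the other wild-type arrays. Fcer2a lost its call without wild-type array 2 (-1.60) or 3 (-1.94), and Serpina1b without wild-type array 3 (-2.23) or NHE3-deficient array 2 (-2.05) or 3 (-1.83). Pnliprp2 (-2.10), Fcer2a (-1.67) and Serpina1b (-2.45) were also not called with NHE3-deficient array 3 alone.

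In all, 1342 probe sets were higher and 1685 lower in NHE3-deficient colon at the limma threshold, 11.2% of those tested. They name 968 genes that rose and 1180 that fell, with 3 genes in both directions. Of the called probe sets, 373 rose and 464 fell at least 2-fold. All 3 arrays of a genotype lay on the same side of all 3 of the other for 32.3% of the probe sets tested, against 10% by chance. The split between directions depended on scaling: with medians set equal on all arrays 2566 probe sets were higher and 825 lower, and with quantile normalization 1337 and 1333. The median log2 fold change of all tested probe sets was -0.10 as deposited, 0.07 with medians set equal and -0.02 after quantile normalization, and every log2 fold change given here is relative to the deposited scale. With NHE3-deficient array 3 alone against wild type, a fit that assumes this array to vary as the wild-type arrays do, 752 were higher and 1265 lower. In that fit Fcer2a (-1.67), Psme1 (0.46), Psmb10 (0.41), Tapbpl (0.55), Etfdh (0.59), B3gnt6 (-0.97) and Chga (-0.39) kept their direction but lost their calls. The same held for Mcm6 (-0.74), Lgr5 (-0.95), Ephb3 (-0.82), Vim (-0.92), Apoa1 (1.78) and Adipoq (-2.36). Leaving out 1 array gave 820 higher without NHE3-deficient array 3. It gave 765, 834, 837 and 1011 lower without wild-type array 3, NHE3-deficient array 3, wild-type array 2 and NHE3-deficient array 1.

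**Figure D2:**
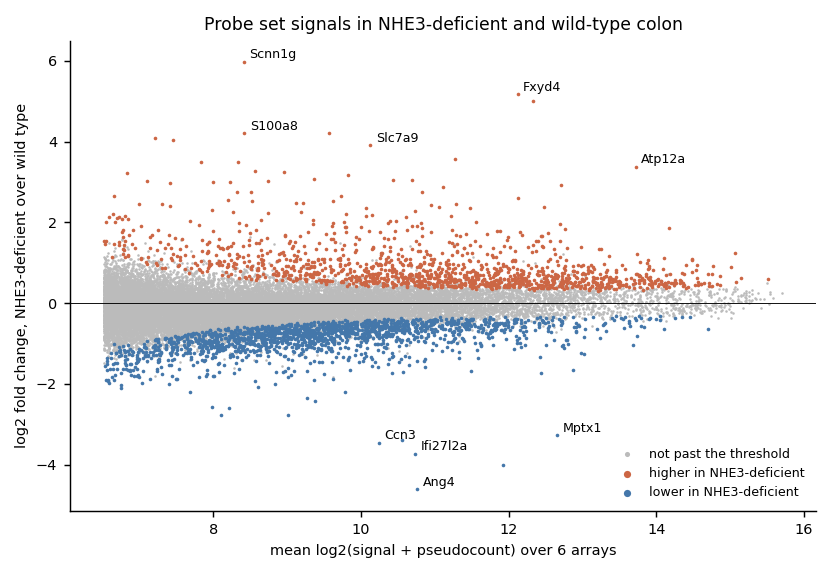
Each point is a tested probe set, with its mean log2(signal + pseudocount) over the 6 arrays on the x axis and its log2 fold change, NHE3-deficient over wild type, on the y axis. Coloured points passed the adjusted p threshold (1342 higher, 1685 lower), with Scnn1g at 5.97 and Ang4 at -4.61 as the extremes.

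Among genes of sodium and potassium channels and the aldosterone response, 9 of 16 measured members rose and 1 fell. Besides Scnn1g, Fxyd4 and Atp12a, the beta subunit of the epithelial sodium channel, Scnn1b, rose from 238 ± 47.7 to 1272 ± 305 (SD, n = 3 each; log2 fold change 2.26, SE 0.20). The alpha subunit Scnn1a rose less, from 1585 ± 266 to 2278 ± 272 (0.52, SE 0.15, adjusted p = 0.042). Hsd11b2, the enzyme that protects the mineralocorticoid receptor from glucocorticoids, rose by 1.33 (SE 0.11), the kinase Sgk1 by 0.99 (SE 0.13), the deubiquitinase Usp2 by 1.05 (SE 0.16) and the receptor chaperone Fkbp5 by 1.40 (SE 0.12). Kcnn4, a calcium-activated potassium channel, had a log2 fold change of -1.25 (SE 0.14). The mean over the list was 1.37 (camera adjusted p = 2.8e-08; fry adjusted p = 0.000348). With an estimated correlation the adjusted p = 0.0835. Adjusted over the list alone, 10 rose and 1 fell. The count was 8 higher and 1 lower with NHE3-deficient array 3 alone.

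**Figure D3:**
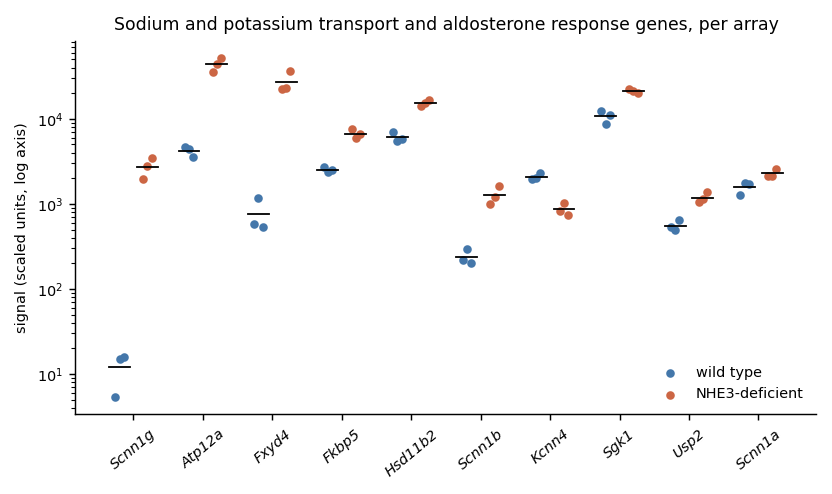
Signals (scaled units, log axis) of the 10 members of the sodium and potassium list with the smallest p, 1 point per array and a line at each group mean (n = 3 per group). Scnn1g, Fxyd4, Atp12a and Scnn1b lay higher on every NHE3-deficient array than on any wild-type array, and Kcnn4 lay lower.

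Among ion exchangers and other epithelial transporters, 8 of 31 measured members rose and 6 fell. The anion channel Best2, found in goblet cells of the colon, rose from 632 ± 60 to 2582 ± 14.8 (SD, n = 3 each; log2 fold change 1.98, SE 0.12). The chloride-bicarbonate exchanger Slc26a3 rose by 0.72 (SE 0.13), the sulfate transporter Slc26a2 by 0.83 (SE 0.11), the phosphate transporter Slc20a1 by 1.35 (SE 0.16), the membrane carbonic anhydrase Car4 by 0.93 (SE 0.15) and the water channel Aqp8 by 0.93 (SE 0.11). The water channels Aqp1 (-1.17, SE 0.12) and Aqp4 (-0.72, SE 0.15) fell. Adjusted over the list alone, 11 rose and 7 fell. The mean of 0.17 did not pass camera (adjusted p = 0.0859, from 0.0409 without NHE3-deficient array 3 to 0.493 over the alternatives; adjusted p = 0.287 with an estimated correlation), and fry gave an adjusted p = 0.0223. The members lower in NHE3-deficient colon numbered 2 without wild-type array 3 or NHE3-deficient array 3, and 3 without wild-type array 2 or NHE3-deficient array 1 or 2 or with medians set equal.

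Antimicrobial and epithelial defence genes moved in both directions, with 12 of 26 measured members higher and 4 lower. The acute phase proteins Saa1 (1.24, SE 0.12), Saa2 (2.15, SE 0.16) and Saa3 (1.88, SE 0.19) rose, as did Pla2g2a, a bactericidal phospholipase (2.39, SE 0.23), Pglyrp1, which binds peptidoglycan (1.22, SE 0.11), Ltf, lactoferrin (2.45, SE 0.29), Slpi, a secreted protease inhibitor (2.44, SE 0.38), and Nos2, the inducible nitric oxide synthase (3.02, SE 0.34). Saa1 signal reached 53132 ± 7809 from 22310 ± 1282 (SD, n = 3 each). Ang4, Mptx1, Itln1 and the lectin Reg4 (-1.74, SE 0.17) fell. The mean was 0.52 and the camera adjusted p = 7.8e-05, and the adjusted p = 0.194 with an estimated correlation. Fry gave an adjusted p = 0.0190, and 15 rose and 4 fell when adjusted over the list alone.

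Of 22 measured inflammatory cytokine, chemokine and adhesion genes, 11 rose and 0 fell. The neutrophil chemoattractants Cxcl1 (1.25, SE 0.20) and Cxcl2 (1.47, SE 0.35) rose, with 2 further Cxcl1 probe sets at 2.74 and 2.22. Ccl20, a chemokine for CCR6-bearing cells, rose by 1.28 (SE 0.24), Il18 by 0.89 (SE 0.11), the interleukin-1 receptor antagonist Il1rn by 1.26 (SE 0.18), and the NF-kappaB inhibitors Tnfaip3 by 1.09 (SE 0.13) and Nfkbia by 0.67 (SE 0.11). The mean was 0.72 (camera adjusted p = 5.7e-08; adjusted p = 0.194 with an estimated correlation; fry adjusted p = 0.0139), and 13 rose when adjusted over the list alone. This list has 38 genes, and without a filter the mean was 0.48. Among neutrophil and mast cell markers, 3 of 5 measured members rose: S100a8 and the mast cell proteases Mcpt1 (2.75, SE 0.30) and Mcpt2 (1.94, SE 0.20). Kit, the stem cell factor receptor, had a log2 fold change of -1.10 (SE 0.18). That list had a mean of 1.71 (camera adjusted p = 0.00334; adjusted p = 0.253 with an estimated correlation; fry adjusted p = 0.0139), and the counts were the same when adjusted over the list alone. Its other 10 genes were below the filter or not on the array, and without a filter the mean was 0.84, below the 1.23 of the sodium and potassium list in that fit.

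Interferon response genes gave 2 higher and 6 lower of 33 measured members. Rsad2 (-1.35, SE 0.21), Irf7 (-0.92, SE 0.15), Ifit1 (-0.99, SE 0.21) and Bst2 (-0.93, SE 0.21), genes of the type I interferon programme, fell, while Ido1, which degrades tryptophan (1.23, SE 0.20), and the transcription factor Irf1 (0.52, SE 0.13) rose. Adjusted over the list alone, 2 rose and 7 fell. The mean of -0.26 did not pass camera (adjusted p = 0.176; adjusted p = 0.787 with an estimated correlation) or fry (adjusted p = 0.507). It was -0.54 (adjusted p = 5.7e-05) with 9 members lower without NHE3-deficient array 2, -0.38 (adjusted p = 0.0257) without wild-type array 3, and -0.50 (adjusted p = 0.000753) with NHE3-deficient array 3 alone. Without NHE3-deficient array 1 it was -0.11 and without array 3 of that group -0.14. Over the alternatives camera gave an adjusted p from 5.7e-05 to 0.767. Ifit1 lost its call without wild-type array 2 (-0.91) or NHE3-deficient array 3 (-0.85), and Bst2 without wild-type array 2 (-0.80) or NHE3-deficient array 1 (-0.88) or 3 (-0.79). Each of these 3 arrays left out gave 3 members lower, and 1 member rose without wild-type array 1 or NHE3-deficient array 2 or 3.

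Of 20 measured genes of antigen processing and presentation, 3 rose and 0 fell, at either adjustment, including when adjusted over the list alone. These were the proteasome activator Psme1 (0.51, SE 0.11), the immunoproteasome subunit Psmb10 (0.54, SE 0.13) and the tapasin-related Tapbpl (0.53, SE 0.14). The class II genes Cd74 (1.21, SE 0.39, adjusted p = 0.071) and H2-Aa (1.37, SE 0.53, adjusted p = 0.12) did not pass, with H2-Aa signals of 2858 ± 1734 and 8117 ± 4960 (SD, n = 3 each). The mean of 0.43 passed camera (adjusted p = 0.000171), but the adjusted p = 0.538 with an estimated correlation and fry gave an adjusted p = 0.212. The mean was 0.28 without NHE3-deficient array 2 and 0.64 without array 1 of that group, past the camera threshold in both. The count was 8 without NHE3-deficient array 1, 1 without wild-type array 1 or 3, 6 with medians set equal, and 5 with NHE3-deficient array 3 alone. Tapbpl held its call in 1 of the 6 fits that left out an array, the fit without NHE3-deficient array 1, with log2 fold changes from 0.43 to 0.57 in the 5 others. Psmb10 lost its call without wild-type array 1 (0.54) or 3 (0.44) or NHE3-deficient array 2 (0.43) and with quantile normalization (0.44).

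Called markers of absorptive cells were all higher on the deposited scale, although with quantile normalization 7 were higher and 1 lower. Called genes of dividing and crypt base cells were all lower. Among absorptive colonocyte markers, 8 of 17 rose and 0 fell, with the bile acid transporter subunit Slc51b at 1.80 (SE 0.11) besides Anpep, Aqp8, Car4 and Slc26a3. The mean was 0.64 (camera adjusted p = 1.4e-07; adjusted p = 0.253 with an estimated correlation; fry adjusted p = 0.0190), with 9 higher when adjusted over the list alone. The count was 5 without wild-type array 2 or NHE3-deficient array 1, and 5 with NHE3-deficient array 3 alone. Of 19 measured proliferation genes, 10 fell and 0 rose, among them Mki67 (-0.82, SE 0.12), the topoisomerase Top2a (-0.83, SE 0.17) and the replication licensing factors Mcm5 (-0.96, SE 0.20) and Mcm6 (-0.73, SE 0.14). That mean was -0.61 (camera adjusted p = 2.6e-06; adjusted p = 0.309 with an estimated correlation; fry adjusted p = 0.0392), with 14 lower when adjusted over the list alone and 6 lower over all probe sets without wild-type array 1 or NHE3-deficient array 1 or 3. Of 12 measured stem and crypt base genes, 6 fell and 0 rose, including Cd44 (-1.57, SE 0.17), the R-spondin receptor gene Lgr5 (-1.20, SE 0.21; signal 324 ± 43.2 to 124 ± 23.6, SD, n = 3 each), Ephb3 (-0.87, SE 0.16) and Sox9 (-1.01, SE 0.22). Sox9 lost its call without wild-type array 3 (-0.87), which left 3 members lower. The stem and crypt base mean was -0.75 (camera adjusted p = 8.1e-05; adjusted p = 0.293 with an estimated correlation; fry adjusted p = 0.0223), with 7 lower when adjusted over the list alone.

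**Figure D4:**
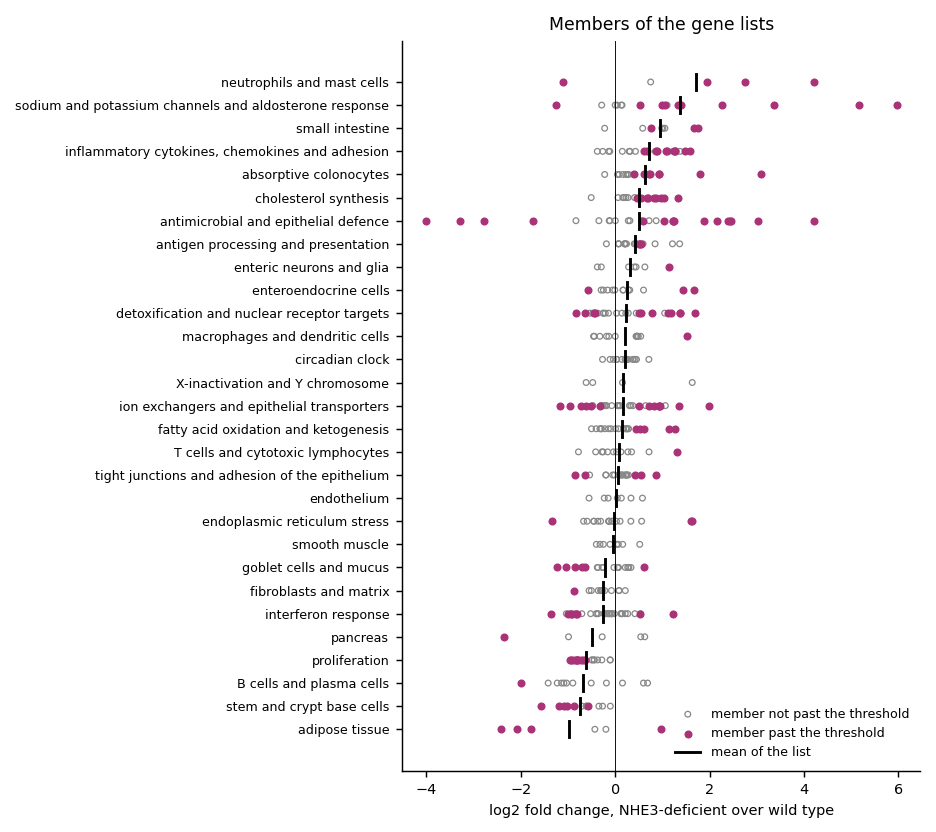
Log2 fold change, NHE3-deficient over wild type (x axis), of each measured member of the 29 lists with over 1 measured member. Filled points passed the adjusted p threshold, open points did not, and the black line is the mean over the members that passed the filter, 1.71 at the highest (5 of 15 genes) and -0.99 at the lowest.

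Goblet cell and mucus genes gave 1 higher and 5 lower of 18, or 2 and 7 when adjusted over the list alone. The goblet cell transcription factor Spdef (-1.05, SE 0.13), the membrane mucin Muc4 (-0.84, SE 0.12), the secreted Spink4 (-0.65, SE 0.11) and the glycosyltransferase B3gnt6 (-1.23, SE 0.24) fell, and the membrane mucin Muc13 rose (0.62, SE 0.11). The mean was -0.21 (camera adjusted p = 0.211; adjusted p = 0.596 with an estimated correlation; fry adjusted p = 0.0803). After quantile normalization that mean was -0.32 (adjusted p = 0.00157, the lowest of the alternatives, which reached 0.826) and 8 members fell. With medians set equal it was -0.041 (adjusted p = 0.282), with 3 higher and 5 lower. Enteroendocrine genes gave 2 higher and 1 lower of 13, with or without adjustment over the list alone. The peptide hormones Pyy (1.66, SE 0.12; signal 3137 ± 383 to 9976 ± 1135, SD, n = 3 each) and Insl5 (1.43, SE 0.19) rose. Chga, a granin, had -0.57 (SE 0.14), a call lost without wild-type array 2 (-0.52) or 3 (-0.56) or NHE3-deficient array 1 (-0.46) or 2 (-0.59) and with medians set equal (-0.40). The enteroendocrine mean was 0.25 (camera adjusted p = 0.206). In tight junctions and epithelial adhesion, 3 rose and 2 fell of 20, or 3 and 3 when adjusted over the list alone, with the cadherin Cdh17 at 0.54 (SE 0.09) and the claudin Cldn15 at -0.85 (SE 0.15). Its mean was 0.06 (camera adjusted p = 0.131; fry adjusted p = 0.0223) and -0.022 after quantile normalization, and 8 members rose with medians set equal. Without wild-type array 1, 2 or 3 or NHE3-deficient array 2 or 3, 1 member of it rose, and 1 fell without wild-type array 3 or NHE3-deficient array 2 or 3.

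Of 16 measured cholesterol synthesis genes, 9 rose and 0 fell, against 8 and 1 with quantile normalization and 6 and 1 with Xist as a covariate. Msmo1, a sterol oxidase, rose by 1.34 (SE 0.16), Insig1, which retains the sterol sensor in the endoplasmic reticulum, by 0.98 (SE 0.14), Sqle, squalene epoxidase, by 0.67 (SE 0.11) and Sc5d by 0.87 (SE 0.14). The mean was 0.52 (camera adjusted p = 3.1e-07; adjusted p = 0.253 with an estimated correlation; fry adjusted p = 0.0190), and 10 rose and 1 fell when adjusted over the list alone. In detoxification and nuclear receptor targets 8 rose and 4 fell of 26, or 9 and 6 when adjusted over the list alone. The cytochromes Cyp4f16 (1.37, SE 0.12) and Cyp2d26 (1.37, SE 0.15) rose and the glutathione transferase Gsta4 fell (-0.83, SE 0.14). The detoxification mean was 0.22 (camera adjusted p = 0.0848) and passed at 0.30 (adjusted p = 0.0248) without wild-type array 3 and at 0.28 (adjusted p = 0.0285) without NHE3-deficient array 2, with an adjusted p up to 0.493 over the alternatives. The members lower numbered 2 without wild-type array 1 or 2 or NHE3-deficient array 2 or 3. In fatty acid oxidation and ketogenesis 5 of 22 rose and 0 fell, also when adjusted over the list alone, including the electron transfer dehydrogenase Etfdh (0.61, SE 0.10). That mean was 0.16 (camera adjusted p = 0.0649), and the count was 1 without NHE3-deficient array 1, 2 without wild-type array 2, 3 without wild-type array 1 or NHE3-deficient array 2 or 3, and 0 with NHE3-deficient array 3 alone. The mean was 0.079 without NHE3-deficient array 1, 0.090 without wild-type array 1, and 0.023 with NHE3-deficient array 3 alone. It passed without wild-type array 3 (0.24, adjusted p = 0.00688) and without NHE3-deficient array 3 (0.22, adjusted p = 0.00886), while the adjusted p reached 0.670 over the alternatives. With medians set equal 10 of its members rose and the mean was 0.33 (adjusted p = 0.0402).

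In endoplasmic reticulum stress, Herpud1 (1.63, SE 0.11) and Creb3l3 (1.62, SE 0.22) rose and Ern2, the stress sensor of mucus-secreting cells, fell (-1.33, SE 0.19). These were the 3 of 18 members past the threshold, with 2 higher and 5 lower when adjusted over the list alone, and the mean was -0.02 (camera adjusted p = 0.772), or 0.15 with medians set equal. Of 15 circadian clock genes, 0 passed the limma threshold at either adjustment, including when adjusted over the list alone, and 2 had an unadjusted p under 0.05. The largest value there was that of Per1 (0.71, SE 0.21, adjusted p = 0.051), and the mean was 0.21 (camera adjusted p = 0.0911). The clock mean passed without wild-type array 3 (0.28, adjusted p = 0.0372) and with quantile normalization (0.31, adjusted p = 0.0436), and was 0.14 without wild-type array 1, with an adjusted p up to 0.174 over the alternatives.

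Gzma, Fcer2a and Cd14 were called among markers of lymphocytes and macrophages. Of 12 T cell and cytotoxic lymphocyte genes, the granzyme Gzma rose (1.31, SE 0.17). The T cell mean was 0.07, the median -0.0030 and the direction given by camera upward (adjusted p = 0.373). Of 12 B cell and plasma cell genes, Fcer2a fell at the threshold over all probe sets and 2 rose and 7 fell when adjusted over the list alone. That mean was -0.67 (camera adjusted p = 0.139), -0.89 (adjusted p = 0.0256) with 6 lower without NHE3-deficient array 1, and -1.05 (adjusted p = 0.0128) with 4 lower with NHE3-deficient array 3 alone. It was -0.50 (adjusted p = 0.0291) with medians set equal and -0.43 (adjusted p = 0.313) without wild-type array 2, and the adjusted p reached 0.384 over the alternatives. The B cell count was 0 lower without wild-type array 2 or 3, and 3 lower without wild-type array 1. Of 13 macrophage and dendritic cell genes, Cd14, the lipopolysaccharide co-receptor, rose (1.51, SE 0.15), and the mean was 0.22 (camera adjusted p = 0.131), 0.36 (adjusted p = 0.0286) without wild-type array 2, 0.11 without NHE3-deficient array 2, and 0.14 without wild-type array 1 or with NHE3-deficient array 3 alone, with an adjusted p up to 0.343 over the alternatives. Each of these lists had the same count adjusted over the list alone, apart from the B cell list.

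No member of the smooth muscle (8 measured) or endothelium (7 measured) lists passed the limma threshold, with means of -0.04 and 0.02 (camera adjusted p = 0.967 and 0.622), although the smooth muscle mean was 0.071 with quantile normalization and 0.14 with medians set equal. At an unadjusted p under 0.05 there were 1 and 0 members. The smooth muscle mean was 0.15 (adjusted p = 0.339) without NHE3-deficient array 3 and -0.42 (adjusted p = 0.227) with that array alone, where 1 member fell. The single red blood cell gene measured had a log2 fold change of -0.19 and did not pass. Of 7 enteric neuron and glia genes, Nos1 rose (1.14, SE 0.30; mean 0.32, camera adjusted p = 0.252), a call lost when any of the 6 arrays was left out (0.95 without wild-type array 2 to 1.24 without wild-type array 3). Of 13 fibroblast and matrix genes, Vim fell (-0.86, SE 0.19; mean -0.26, camera adjusted p = 0.211). The Vim call was lost without wild-type array 2 (-0.65) or NHE3-deficient array 3 (-0.83). Of 6 adipose tissue genes, 3 fell and 1 rose: Car3 (-2.42), Fabp4 by its representative probe set (-2.08, SE 0.53) and the adipokine Adipoq (-1.77, SE 0.51) fell, and Cidec, a lipid droplet protein, rose (0.97, SE 0.25). The adipose mean was -0.99 (camera adjusted p = 0.160), with 4 lower when adjusted over the list alone. The mean was -0.65 without wild-type array 2. The adipose list had 0 called members without wild-type array 2 and 1 lower without wild-type array 1 or NHE3-deficient array 1 or 3. Fabp4 was at -1.48 and Adipoq at -1.15 without wild-type array 2. Of 5 pancreas genes, Clps fell (representative probe set -2.36, SE 0.24; mean -0.49, camera adjusted p = 0.373), with a mean of -0.28 without wild-type array 1. Of 8 genes typical of small intestine, 3 rose: the retinol-binding Rbp2 (1.75, SE 0.20), the glucose transporter Slc5a1 (0.76, SE 0.10) and the apolipoprotein Apoa1 (1.67, SE 0.42). That mean was 0.95 (camera adjusted p = 0.000326; adjusted p = 0.287 with an estimated correlation; fry adjusted p = 0.0838), with 5 higher when adjusted over the list alone. The Apoa1 call was lost without wild-type array 2 (1.71) or NHE3-deficient array 2 (1.603) or 3 (1.62), and 5 members rose without wild-type array 3. In the other lists of this paragraph the counts adjusted over the list alone were the same.

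The share of called probe sets around Slc9a3 was compared with the share elsewhere. Within 20 Mb of the gene on its chromosome, by the gene order of assembly GRCm38.p6, 32 of 298 tested probe sets passed, 10.7% (exact Clopper-Pearson 95% interval 7.46 to 14.8%), among them both Slc6a19 probe sets (3.25 and 3.00). Of all other positioned probe sets, 2706 of 22456 passed, 12.1%. The odds ratio was 0.878 (Fisher's exact test, two-sided p = 0.531). A share over the whole window cannot tell whether a single gene in it, such as Slc6a19, changed through its position. Fisher's test and the interval treat probe sets as independent, although several can name the same gene, as those of Slc6a19 do. With the plain equal-variance test, which called far fewer, the share near the gene was higher: 5 of 298, 1.68%, against 113 of 22456, 0.503%, elsewhere (odds ratio 3.37, Fisher's exact test, two-sided p = 0.0197), and over the alternatives p ran from 0.0197 to 1.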

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

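Among the tests here, the comparison with proliferation genes and the iron shortage list without its 2 highest members were chosen only after the result was seen.

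The array carries control probe sets for the mouse transcripts Tfrc, the transferrin receptor that imports iron, and Pcx, pyruvate carboxylase, and these controls were left out of the comparison of genotypes. Their signal was higher in NHE3-deficient colon than in wild type. The 3 Tfrc controls had log2 fold changes of 1.84 (3' probe set), 1.98 (5' probe set) and 1.74 (middle probe set). The regular Tfrc probe sets rose as well, by 1.92, 1.82 and 1.39. The 4 Pcx controls had log2 fold changes of 1.06 (3'), 1.13 (5'), 1.25 and 1.501 (the middle pair), and the regular Pcx probe set rose by 0.95 (SE 0.13).

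For Tfrc, more dividing cells, which carry more transferrin receptor, would raise the proliferation genes, and these had a mean log2 fold change of -0.61. A response to a shortage of iron may raise Tfrc: 11 genes of that response, without Tfrc and Steap4, whose rises had been seen, had a mean of 0.51 (SD 0.73; limma fry adjusted p = 0.00766 over the 4 lists of the closing tests), past the limits set beforehand of 0.5 for the mean, by far less than the spread, and 0.05 for p. Of these 11 genes, 5 rose and 0 fell: Bnip3 (2.04), Egln3 (1.66), Slc11a2 (0.57), Slc40a1 (0.45) and Heph (0.43), while Ndrg1 had -0.46 (adjusted p = 0.167). Other Slc11a2 probe sets had 0.02, 1.51 and 1.39, and other Ndrg1 probe sets -0.61, -0.28, -0.24 and -0.66. Ankrd37 (0.51, limma adjusted p = 0.0943) and Cybrd1 (-0.06) did not pass. Without Bnip3 and Egln3, whose removal must lower the mean, the other 9 had a mean of 0.21 (SE 0.11 over the members). By less than this SE, that mean is under the 0.25 set beforehand, for all 11, as evidence against. For these 9, limma fry gave an unadjusted p = 0.0241 upward. Low oxygen, which also induces Bnip3 and Egln3, and a direct effect of the genotype stay open and untested. Vegfa (0.24, with another probe set at 0.81), Slc2a1 (0.13) and Pdk1 (0.10), which low oxygen induces too, did not pass. They belong to the same list of 11, so their values do not separate a shortage of iron from low oxygen.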

How the results depend on the processing

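The fits with NHE3-deficient array 3 alone and with Xist as a covariate were chosen only after the data were seen. No alternative reversed a named gene: over 121 called probe sets of named genes, 1816 results kept their side of the threshold and 347 lost it, of which 107 were under the plain equal-variance test and 47 without the mean-variance trend. The fit with Xist as a covariate is not used for Xist or its list, since it adjusts for Xist itself. Signal over background limits dim transcripts, whose fold changes move with the pseudocount. The cause was not tested for the changes below, except that fewer arrays or a stricter threshold give fewer calls by construction. Replicate numbers did not pair the arrays: same-numbered arrays had residual correlations of 0.026, -0.038 and 0.0034, 1 of 6 arrays correlated best with its own number, and a fit with the replicate number as a block called 1156 higher and 1384 lower, with the adipose list past the threshold (-0.99, adjusted p = 0.0123) and Nos1 no longer called.

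Higher and lower counts were 2566 and 825 with medians set equal, 511 and 558 without the trend, 86 and 43 under the plain test, and 373 and 464 at least 2-fold. At an adjusted p under 0.1, 2942 were lower, and with array 3 alone 752 were higher. Leaving out each array gave 820 to 1212 higher and 765 to 1372 lower. Of the 3027 calls, 2265 (74.8%) were shared with quantile normalization, 2167 (71.6%) with medians set equal, 1433 (47.3%) with array 3 alone and 1584 (52.3%) with the Xist covariate. The share near Slc9a3 was 1.68% under the plain test. The Slc9a3 log2 fold change was -0.72 with array 3 alone, -0.76 with the covariate and -0.61 to -0.26 without each array. The interferon mean was -0.50 with array 3 alone, -0.49 with the covariate and -0.54 to -0.11 without each array. With an estimated correlation none of the 30 lists passed (lowest adjusted p = 0.0835). The calls lost were those of the sodium (1.37), antigen (0.43), antimicrobial (0.52), inflammatory, cholesterol, proliferation, stem, colonocyte, neutrophil and small intestine lists. The antigen (0.43) and small intestine lists did not pass fry either.

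Means of lists that were not called changed sign as follows. Smooth muscle was 0.060 at the higher pseudocount, 0.095 without a filter, 0.071 with quantile normalization, 0.14 with medians set equal, 0.028 with array weights and -0.16 to 0.15 without each array. Endothelium was -0.014 at the higher pseudocount, -0.12 without a filter, -0.021 with array weights, -0.019 over all probe sets of a gene and -0.045 to 0.13 without each array. Endoplasmic reticulum stress was 0.15 with medians set equal, 0.034 with array 3 alone, 0.042 with the covariate and -0.058 to 0.0075 without each array. T cells ran from -0.079 to 0.30 without each array, tight junctions were -0.022 with quantile normalization, and X and Y genes were -0.16 with array 3 alone. With medians set equal, means were 0.34 for ion exchangers, -0.090 for interferon, 0.23 for tight junctions, 0.39 for detoxification, 0.38 for the clock, -0.041 for goblet, 0.43 for enteroendocrine, 0.39 for macrophage, -0.086 for fibroblast and -0.32 for pancreas lists.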

Other observations

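The tests chosen only after the result was seen in this part are the amino acid absorption list and its repeat without 3 members, the comparison of NHE3-deficient array 3 with the others, the fits with array 3 alone and with Xist as a covariate, and the comparison of epithelium with muscle. The Hox lists were drawn up before their own results were seen, but after falls of other Hox cluster genes had been seen.

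Genes that absorb amino acids and peptides, a list drawn up after Slc7a9, Slc6a19 and Anpep had been seen among the largest increases, had called members that were all higher in NHE3-deficient colon. Of 19 measured members, 8 rose and 0 fell, or 12 and 1 when adjusted over the list alone. Besides these 3 genes, the proton-coupled amino acid transporter Slc36a1 rose by 2.02 on the log2 scale (SE 0.14) and the aminopeptidase Enpep by 1.77 (SE 0.23). The peptide transporter Slc15a1 rose by 1.01 (SE 0.16), the meprin subunit Mep1b by 0.58 (SE 0.10) and the dipeptidyl peptidase Dpp4 by 0.49 (SE 0.12). Other Dpp4 probe sets had -0.12, -0.03 and 0.45. Slc6a19 lies within 20 Mb of Slc9a3, and an effect of that position on its signal was not tested. Without the 3 genes that prompted the list, whose choice keeps its direction from being independent evidence, 5 of the other 16 rose and 0 fell, with a mean of 0.55 (SE 0.17 over the members). Beside it 3 of 8 measured small intestine markers rose, Rbp2 (1.75), Slc5a1 (0.76) and Apoa1 (1.67), whose call was lost without wild-type array 2 (1.71) or NHE3-deficient array 2 (1.603) or 3 (1.62); that list did not pass camera at an estimated correlation (limma adjusted p = 0.287) or fry (adjusted p = 0.0838).

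Some position genes of the Hox clusters, in a posterior and an anterior list, also differed. These lists were drawn up after falls of Hoxa7 and Hoxd3os1 had been seen, and leave them out. Hoxb13 rose from 3569 ± 785 to 10395 ± 2243 (SD, n = 3 each; log2 fold change 1.54, SE 0.18), Hoxa13 rose by 1.08 (SE 0.23) and Hoxd13 by 0.86 (SE 0.23), all of the group expressed at the hindmost end of the body. Of 7 posterior Hox genes measured these 3 rose and 0 fell (limma fry adjusted p = 0.0143). Of 8 anterior Hox genes 1 fell, Hoxb3 (-0.83, SE 0.20), and 4 fell when adjusted over the list alone (limma fry adjusted p = 0.00766). These 4 were Hoxb3, Hoxd8 (-0.85), Hoxa5 (-0.55) and Hoxa3 (-0.62). Other probe sets were also negative for Hoxb3 (-0.69), Hoxd8 (-0.50) and Hoxa3 (-0.47 and -0.33), but another Hoxa5 probe set had 0.43. Hoxb4, not called at -0.58, had another probe set at 0.27.

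The channel, antimicrobial and mucosal genes that moved most were weighed against a change in which tissue was sampled. A lower share of epithelium against muscle would lower colonocyte markers and raise smooth muscle. The colonocyte markers, which include Anpep from the largest increases, had a mean of 0.64. The smooth muscle mean was -0.04, 0.15 without NHE3-deficient array 3, -0.42 with that array alone and -0.44 with Xist as a covariate. The opposite change, a higher share of epithelium, was not tested. More distal colon in the NHE3-deficient samples may account for part of the pattern. The posterior Hox genes had a median of 0.33 and the anterior ones of -0.58. The anterior median met its limit set beforehand for this explanation. That list was drawn up after falls of Hoxa7 and Hoxd3os1 had been seen in these data, so its direction is not independent evidence. The posterior median lies between the limits set beforehand of 0.5 for this explanation and 0.25 against it. Of the posterior genes, Hoxd11, Hoxd10 and Hoxa11 were dim, with wild-type mean signals of 92.2, 129 and 185. Of 8 small intestine markers 3 were called higher, in a list that did not pass camera at an estimated correlation (limma adjusted p = 0.287) or fry (adjusted p = 0.0838), and they were not part of these tests. The labels say whole colon, and a difference in sampled region cannot be told apart here from an effect of the genotype on the same tissue.

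The number of called probe sets was weighed against grouping, sex and scaling. The real grouping gave 3027 called probe sets and the highest of the other 9 splits gave 0, so 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. Each of the other 9 splits mixes the genotypes, so a genotype difference widens its residual spread and lowers its calls. Their 0 calls therefore do not measure what grouping alone would give. NHE3-deficient arrays 1 and 2 held Xist together with Y-linked signal, as RNA of both sexes would give, but among 1162 probe sets called between them and wild-type arrays 1 and 2, the difference of NHE3-deficient array 3 from wild-type array 3 had a median ratio of 1.08 (25th to 75th percentile 0.780 to 1.36), with 96.3% in the same direction. This argues against female RNA as the whole source of these calls. For scaling by the authors, 74.8% of the called probe sets were called again after quantile normalization, just short of the 75% set beforehand as evidence against it, so a part of the calls may depend on scaling.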
